A study of Solanum lycopersicum with 2 samples.

How the data were processed

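Gene expression was measured in young primary leaves of tomato seedlings, in 1 library of SlRBZ overexpressing plants and 1 of wild-type plants. Per the labels' protocols, leaves were frozen in liquid nitrogen, total RNA was extracted with TRIzol, and libraries were made by standard Illumina protocols. The submitters' processing notes name TopHat, a spliced aligner. Its version, the counting tool, the gene annotation and the genome build are not given in the sources used here. Per the file headers, the authors deposited expression as FPKM (fragments per kilobase of locus and per 1 M fragments, M standing for mega) for each locus and library. The table held 22315 loci with chromosome, strand, start and end, of which 17803 carried a gene and 4512 did not. Coordinates are those of the table, on 12 chromosomes and a set of unplaced sequence numbered 0. Both value columns were tied to a sample by its title, and 0 columns of values were left untied.

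A gene symbol stood at 954 gene loci (931 distinct symbols), and the others carried an identifier only. Of these symbols, 837 occurred in a reference gene table, which was otherwise only searched for RBZ symbols and for the identifiers of the loci. At 871 loci the table joined 2 or more genes, up to 30, so that their FPKM could not be split. Genes were named only where the table gives a symbol. Gene lists for pigment synthesis, photosynthesis, hormones, growth, defence, clock, light signalling, reference genes and markers of other cell types were fixed before the data were examined, as identifiers recalled from the tomato annotation and product words. The table holds no product descriptions, so the product words and a comparison of product families were not used here. In place of the words, symbols of the table were assigned to the lists from their names. This was done after the table had been opened and a few values (RBCS-1, RBCS-2A and RBCS-3B among them) had been displayed, and before any difference was computed. It departs from the plan fixed in advance, which called for identifiers only where product descriptions were missing. The photosystem, cell expansion, cell division, ethylene and auxin lists rest wholly on these symbols. Where the table gives a symbol it omits that gene's identifier. The setting with fixed identifiers only therefore kept just the loci shown without a symbol, and fixed genes shown by symbol dropped out of it. Of 43 fixed identifiers whose symbol the table gives, 41 lay between their neighbouring identifiers, and the other 2 are the CRTR-B1 and CRTR-B2 pair, whose aliases had been interchanged within the same list. Lists of plastid ribosome, cytosolic ribosome and RanBP2-type zinc finger genes had no measured member and were not analysed here.

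FPKM keeps the depth where whole fragments were counted. Among gene-free loci of equal length (at least 4 loci per length, 300 bp or longer), low values were multiples of a common step, which was fitted as 1 fragment over the scaling total and the length less an offset. With a tolerance of 0.01, 89.3% of 1093 values in the overexpressor and 89.0% of 1019 in wild type were whole. This share is high partly by selection, since a step was accepted only where most values of that length were whole. Lengths off the fitted line were dropped too, which kept 171 of 210 lengths in the overexpressor and 169 of 220 in wild type. The totals were 14.2 M and 7.47 M, a ratio of 1.91, with an offset of 199 bp in both libraries. At an effective length of 1 kb, 1 FPKM was worth 14.2 fragments in the overexpressor and 7.47 in wild type. No count test was run on these recovered fragments. The 5 most abundant gene loci took 34.1% of the FPKM of gene loci in the overexpressor and 47.3% in wild type. In wild type 663 loci were at 0, and in the overexpressor 76. An exact 0 can be a failed estimate, so it is reported as listed and given no fold. Loci at 0 in 1 library still entered the counts of higher and lower loci.

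Differences were taken as log2(FPKM + 1) in the overexpressor minus wild type, over loci with a mean of at least 1 FPKM. A locus was called higher or lower at a difference of 1 (2-fold) or more. With 1 library per genotype no test, p-value or error between replicates was possible, as the design fixed in advance. Each list of at least 3 measured loci was placed by its median among 10000 random lists of the same size, matched on mean expression in 20 bins, with seed 7. A list was called lower or higher outside the central 95% of these medians. Named genes followed a rule fixed in advance: the 8 largest differences in each direction, up to 4 members of each list with the largest differences (among those with a symbol), any member of the chlorophyll, carotenoid and gibberellin synthesis lists, and each reference gene. The rule's clause on genes with a described product was read as genes with a symbol. Its clause on SlRBZ was not used here, since neither the table nor the reference table gives a symbol with RBZ.

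The calculation was tested on simulated fragments for 17631 genes, 200 of which were changed 4-fold, at the recovered depths and an effective length of 1 kb. It recovered 96% of the raised and 98% of the lowered genes, called 8 unchanged genes, and called 3 when nothing was changed. This covers counting noise only. Alternatives fixed in advance were pseudocounts of 0.1 and 0.01, no filter or a filter at 5 FPKM, a 4-fold limit, unmatched random lists, fixed identifiers only, and 5 other scalings (equal sums of 1 M, equal medians, equal upper quartiles, a trimmed mean of log ratios, and scaling without the 100 most abundant genes). Added after seeing the data were named members only, no loci at 0, no loci joining several genes, and random lists from the 50 loci nearest in mean expression. For that last setting the loci of the list itself were not left out of the draw. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.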

Results

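Leaf transcriptomes were compared between tomato (Solanum lycopersicum) seedlings overexpressing SlRBZ and wild-type seedlings. RNA came from young primary leaves, and 1 library per genotype was analysed here. The series title ties the transgene to yellowed, short plants through the chlorophyll, carotenoid and gibberellin pathways, so these pathways were examined first. Although the design text speaks of duplicate evaluation, no second library of either genotype was analysed here, and no difference has a replicate check. The sources used here do not say whether each library was made from pooled duplicates, so what the values and counting intervals stand for is open in that respect. The level of SlRBZ itself was not analysed here, so the genotype labels have no check from the transgene. Values are FPKM per locus, as deposited. The low values moved in whole steps of 1 fragment, which gave scaling totals of 14.2 M (mega) fragments for the overexpressor and 7.47 M for wild type. At 10 FPKM and an effective length of 1 kb, 95% Poisson intervals ran from 8.42 to 11.8 FPKM in the overexpressor and from 7.87 to 12.5 FPKM in wild type. These intervals cover counting error only.

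Of 17631 gene loci with a mean of at least 1 FPKM, 2043 (11.6%) were at least 2-fold higher in the overexpressor and 2647 (15.0%) were at least 2-fold lower. Of the gene lists, 8 had medians called lower against random lists. They cover photosynthesis, pigments, gibberellin synthesis, and carotenoid cleavage with both synthesis and breakdown of abscisic acid. The photosystem and Rubisco calls were lost against the 50 loci nearest in expression, and the gibberellin synthesis call without the filter on low values. The setting with fixed identifiers only kept just the loci shown without a symbol. In it the carotenoid call (4 of 16 loci) and the isoprenoid call (6 of 15) were lost. The isoprenoid call was also lost at equal sums, and the cleavage and abscisic acid call with named members only. Lists of pathogenesis-related, flavonoid, heat shock, ethylene, cell expansion and cell division genes had medians called higher. The heat shock and ethylene calls were lost at equal sums, and the ethylene call also at smaller pseudocounts. Cell expansion lost its call without loci joining several genes. The photosystem, ethylene, cell expansion and cell division lists rest wholly on symbols assigned after the data had been opened. Among 278 loci with a mean of at least 1000 FPKM, 163 were lower and 13 were higher. Folds and differences are on the log2(FPKM + 1) scale, which understates the change of low genes, and all differences are overexpressor minus wild type. Paired values are FPKM in wild type, then in the overexpressor. The median of all gene loci was −0.05, with quartiles of −0.60 and 0.47. The split of higher against lower loci followed the scaling, given here with its log2 scaling factor, which acts before 1 is added and so moves low loci less: 2709 against 1926 at equal upper quartiles (0.25), 4776 against 1133 when scaled without the 100 most abundant genes (0.67), and 9541 against 24 at equal sums (2.92, with a median of 1.08 over all loci). At equal sums the medians of all 8 lists called lower lay above 0, and those values stand beside each list. That scale was set largely by a 34 bp locus without a gene, which held 89.8% of the wild-type sum. Under the other scalings the medians of these 8 lists stayed below 0. Of 107 named loci, 17 lost a 2-fold difference when scaled without the 100 most abundant genes, among them GGPS2, CYP707A1, GA2OX2, PHYB2, PHYE, COP1, TPS7, TPS41 and PR-5. Each list median was placed among those of 10000 random lists of the same size matched on mean expression, which describes these 2 libraries and is no test between genotypes.

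**Figure D1:**
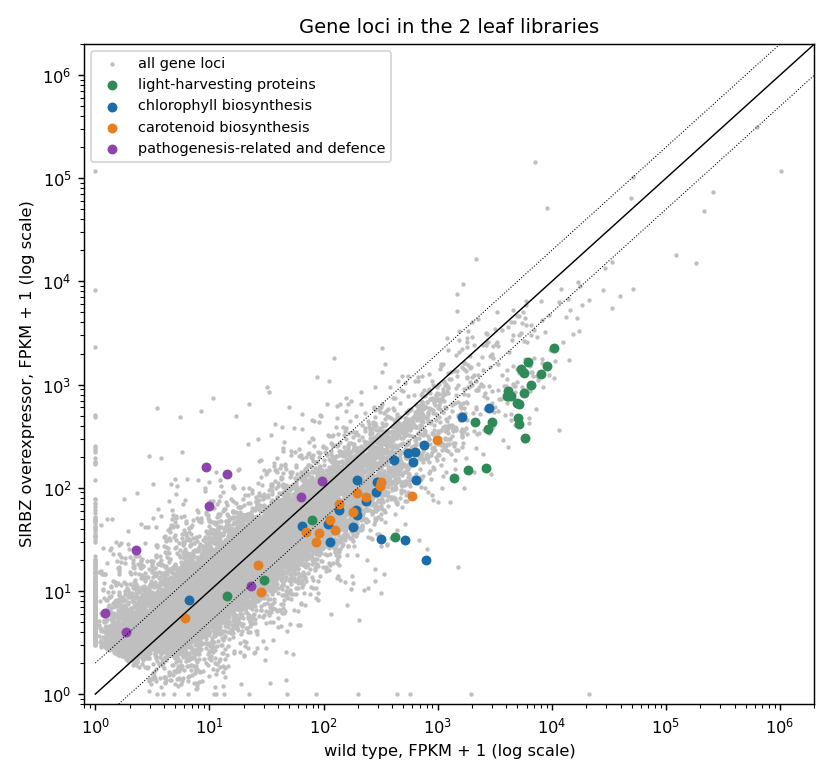
FPKM + 1 of each gene locus in wild type (x axis) and in the SlRBZ overexpressor (y axis), both on log scales, with 4 gene lists in colour. The solid line marks equal values and the dotted lines 2-fold differences on this scale; 24 of the 26 light-harvesting loci lie below the lower dotted line, and their median was −2.69 on the deposited scale, −2.03 without the 100 most abundant genes and 0.23 at equal sums.

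The chlorophyll biosynthesis list was lower in the overexpressor nearly throughout: 20 of 23 measured loci were at least 2-fold lower and none was higher. Its median difference was −1.67 (1.07 at equal sums), at percentile 0.03 of the random lists (0.165 at equal sums). The table gives these loci by identifier only. Solyc12g013710.1 (chromosome 12, 4544984 to 4547480) read 782.5 FPKM in wild type and 19.0 in the overexpressor, a 39.2-fold difference. Solyc10g006900.2 (chromosome 10, 1335129 to 1338824) read 521 and 30.1 FPKM, 16.8-fold lower. The 3 loci that passed neither limit differed by 0.29, −0.62 and −0.72. Genes of chlorophyll breakdown did not move as a group, with 2 of 10 loci higher, 4 lower and a median of −0.55 at percentile 18.2. SGR1, the STAY-GREEN gene that promotes chlorophyll loss, read 25.4 FPKM in wild type and 110 in the overexpressor (chromosome 8, 60579438 to 60582066), while RCCR, a reductase of chlorophyll catabolites, read 45.5 and 25.4. The identifiers of these lists come from memory of the tomato annotation and were not looked up in a table.

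Carotenoid synthesis was lower at 12 of 16 loci and higher at none. ZE, zeaxanthin epoxidase (chromosome 2, 46947558 to 46953170), showed the largest difference of the list, from 597 FPKM in wild type to 81.8 in the overexpressor, 7.22-fold. Both phytoene synthases, which open the pathway, were lower: PSY1 (chromosome 3, 8605225 to 8610361) read 317 and 114 FPKM, and PSY2 (chromosome 2, 39913075 to 39917007) 237 and 79.8. The desaturases PDS (84.7 and 29.0) and ZDS (113 and 47.2), the isomerase CRTISO (179 and 57.8), and the lycopene cyclases LCY1 (311 and 103.5) and LCY-E (125 and 38.0) were lower as well. The carotene hydroxylases CRTR-B1 (990.0 and 287), CYP97A29 (89.6 and 35.2) and CYP97C11 (197 and 88.1) were also at least 2-fold lower, whereas the low CRTR-B2 read 5.09 and 4.42. The list median was −1.49 (1.099 at equal sums), at percentile 0.05 (0.51 at equal sums). With members by fixed identifier only, the median of −0.95 lay at percentile 4.90, which ended the call. That setting kept only the 4 loci shown without a symbol, so PSY1, PSY2, PDS, ZDS and ZE, also fixed by identifier, dropped out. The 12 named loci alone had a median of −1.54 at percentile 0.47. Scaled without the 100 most abundant genes, the differences of PSY1, PSY2, PDS, ZDS, LCY1, CRTISO, CYP97A29 and CYP97C11 were under 2-fold.

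Upstream of the carotenoids, 10 of 15 loci of the plastid isoprenoid (MEP) pathway and its prenyl diphosphate steps were lower and 2 were higher. DXS, which encodes the entry enzyme of the pathway (chromosome 1, 69258969 to 69263260), read 428 FPKM in wild type and 99.5 in the overexpressor, 4.27-fold lower. GGR read 1822 and 452 FPKM, and GGPS2 15.2 and 4.90. In the other direction, the IPI locus on chromosome 5 (64415817 to 64419127), an isopentenyl diphosphate isomerase, read 326 and 2263 FPKM, 6.92-fold higher. The median was −1.36 (1.24 at equal sums), at percentile 0.28. This position was lost at equal sums (6.26) and with fixed identifiers only (3.90), which kept 6 of the 15 loci.

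Downstream, the list of carotenoid cleavage and of abscisic acid synthesis and breakdown held 5 lower and 1 higher loci among 11. NCED1, the dioxygenase that limits abscisic acid synthesis, read 44.0 FPKM in wild type and 7.25 in the overexpressor, 5.46-fold lower. CYP707A1, an abscisic acid hydroxylase that acts in its breakdown, read 47.8 and 15.5. NCED2 was 2.14-fold higher, at 28.8 and 62.8 FPKM. CCD1A, a carotenoid cleavage dioxygenase, read 52.2 and 27.2. The median was −0.92 (0.70 at equal sums), at percentile 0.715. With the members named in the table alone it was −0.56 at percentile 5.84, which ended the call. Since the list mixes synthesis and breakdown, its median gives no direction for abscisic acid itself.

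Gibberellin synthesis rested on 5 measured loci, 3 of them lower and 1 higher. GA20OX1, an oxidase of the later steps (chromosome 3, 1408533 to 1410323), read 119 FPKM in wild type and 17.8 in the overexpressor, 6.39-fold lower. The other lower loci, given by identifier, read 23.9 and 1.56 FPKM (chromosome 6) and 147 and 32.2 FPKM (chromosome 12). Solyc01g080900.2 was 5.97-fold higher, at 7.47 and 49.6 FPKM, and LE3OH-2, a hydroxylase of the final step, read 8.64 and 15.8. The median was −2.16 (0.54 at equal sums), at percentile 0.01. When loci under 1 FPKM were kept it was −0.68 at percentile 3.95, which ended the call. Of 8 inactivating oxidases fixed in advance, 2 had a mean of at least 1 FPKM, at low values. GA2OX2 read 4.86 FPKM in wild type and 1.58 in the overexpressor, 2.27-fold lower. SLGA2OX4 read 0.616 and 8.17, 5.67-fold higher. In gibberellin perception and response, 2 of 8 loci were higher and none lower (median −0.01, percentile 68.0). GID1, a gibberellin receptor (chromosome 9, 61555421 to 61557316), was 10.7-fold higher at 3.68 and 49.3 FPKM. GAI, which encodes a DELLA repressor, read 152 and 87.9, SPY 17.55 and 17.42, and the gibberellin-stimulated GAST1 113 and 144.

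**Figure D2:**
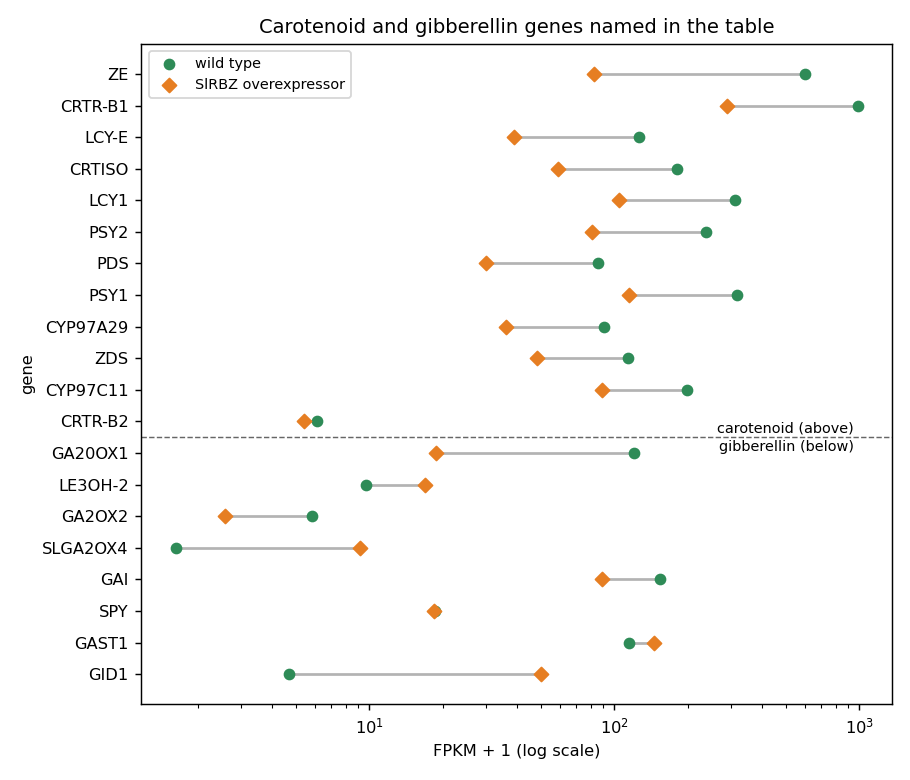
FPKM + 1 (x axis, log scale) of the carotenoid genes (above the dashed line) and gibberellin genes (below it) that the table names, with 1 point per library. Of the 12 carotenoid genes, 11 lie at least 2-fold lower in the overexpressor on the deposited scale, and GID1 (3.68 and 49.3 FPKM) and SLGA2OX4 (0.616 and 8.17 FPKM) lie higher; at equal sums the carotenoid list median moved from −1.49 to 1.099.

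Genes of the photosynthetic apparatus showed the lowest list medians. In the light-harvesting list, 24 of 26 loci were at least 2-fold lower and none was higher. CAB5 (chromosome 12, 693217 to 694583) read 5849 FPKM in wild type and 305 in the overexpressor, 19.1-fold lower, and CAB1D (chromosome 2, 35097556 to 35098501) read 5127 and 416, 12.3-fold lower. Its 5 CAB1B loci on chromosome 2 are near-identical copies, among which reads can divide, and their values (5189 and 644 FPKM at the most different locus) are uncertain singly. The median of −2.69 (0.23 at equal sums) lay below all 10000 random lists, whose lowest was −2.21, and stayed below all of them at equal sums. The list took 2.25% of the FPKM of gene loci in wild type and 0.768% in the overexpressor.

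Photosystem and electron transport genes were lower at 7 of 8 loci, with a median of −2.35 (0.57 at equal sums) at percentile 0.23. The percentile was 8.60, which ended the call, when random lists came from the 50 loci nearest in mean expression. Those loci could include the list's own and those of other photosynthesis lists. With the chlorophyll, carotenoid, light-harvesting and photosystem loci left out of the draw it was 3.54, still without a call. PSBQ read 6416 FPKM in wild type and 858 in the overexpressor, PSBO 7351 and 1209.9, PSBS 6834 and 1222, and PSBP 4347 and 834. These encode proteins of photosystem II, PSBS being the one that acts in heat dissipation. FERREDOXIN, chosen after its values were seen as the exception, read 21.9 and 24.2. In the Rubisco and Calvin cycle list 6 of 7 loci were lower, with a median of −2.41 (0.51 at equal sums) at percentile 0.345. It was at 3.33, without a call, against the 50 nearest loci, which could again include the list's own. The Rubisco small subunit genes RBCS-3B (121997 and 18085 FPKM), RBCS-2A (51548 and 8383) and RBCS-1 (33812 and 5571) were 6.75, 6.15 and 6.07-fold lower, as similar copies that can share reads, and SBPASE, a Calvin cycle phosphatase, read 4639 and 967. That list took 4.71% of the FPKM of gene loci in wild type and 1.56% in the overexpressor.

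Light signalling genes did not move as a group: 5 of 23 loci were lower and 1 was higher (median −0.33, percentile 27.8). ELIP, an early light-induced protein gene, was 4.68-fold higher at 156 and 736 FPKM. The phytochrome genes PHYB2 (51.1 and 20.9) and PHYE (32.4 and 13.2) and COP1, a repressor of light responses (125 and 57.9), were at least 2-fold lower. Of 7 clock loci, all given by identifier, 3 were lower and 1 was higher (median −0.63, percentile 7.98).

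**Figure D3:**
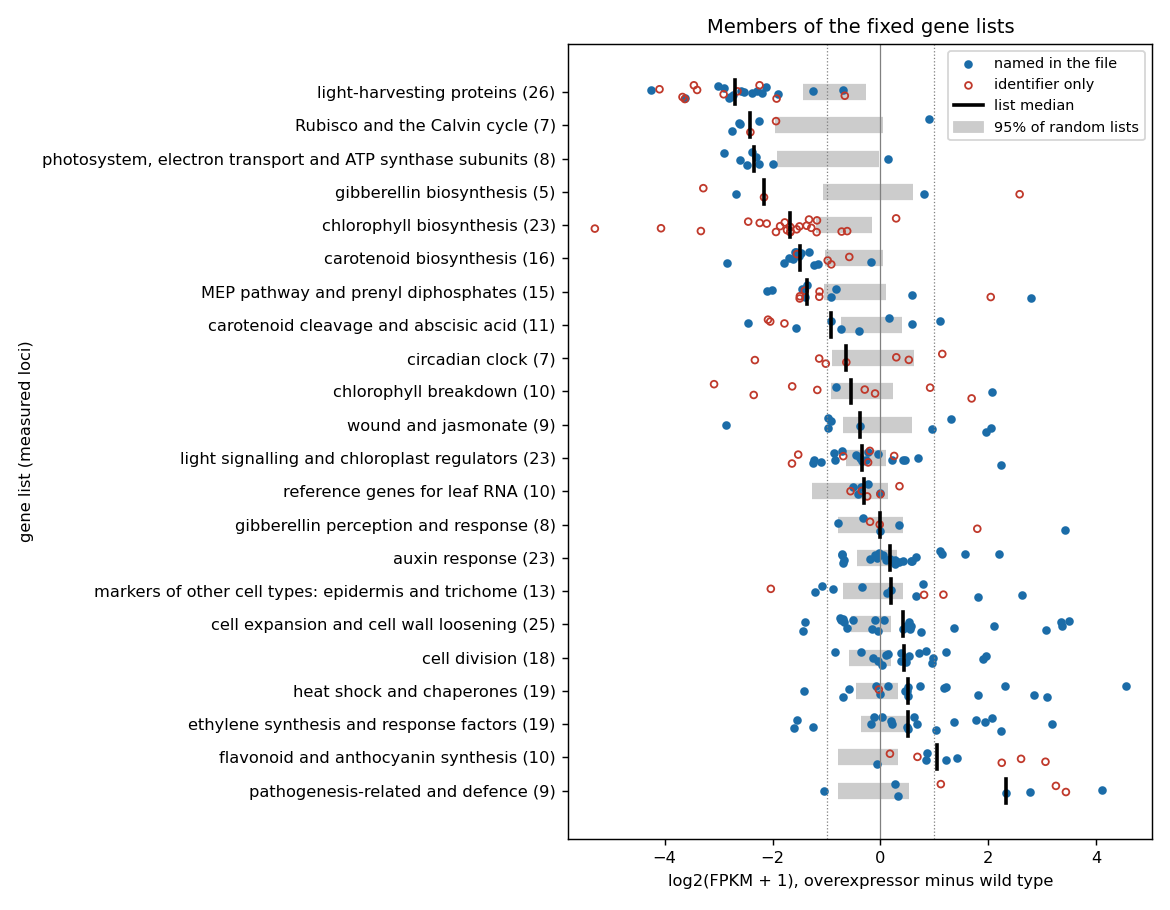
Difference in log2(FPKM + 1), overexpressor minus wild type (x axis), for each measured locus of the gene lists (y axis, number of loci in brackets). Points are loci, filled where the table gives a symbol, black bars are list medians, grey bars hold 95% of the medians of random lists, and dotted lines mark 2-fold; medians run from −2.69 for light-harvesting proteins to 2.32 for defence genes, and at equal sums they became 0.23 and 2.39.

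In the pathogenesis-related list, 6 of 9 loci were at least 2-fold higher and 1 was lower. The median of 2.32 lay above all 10000 random lists. It was 1.33 at percentile 99.94 with named members only, and 3.25 over the 3 loci kept by fixed identifiers only. The chitinase genes CHI3 (chromosome 2, 41128832 to 41129990) and CHI9 (chromosome 10, 52891781 to 52893261) read 8.29 and 8.83 FPKM in wild type and 159 and 66.0 in the overexpressor, 17.2-fold and 6.82-fold higher. CHI2 read 0.221 and 5.09, and PR-5 was 2.08-fold lower at 22.1 and 10.1. For flavonoid and anthocyanin synthesis, 5 of 10 loci were higher and none lower (median 1.05, above all random lists). The median was 2.25 over the 5 loci kept by fixed identifiers only. F3H, flavanone hydroxylase, read 34.1 and 92.6 FPKM, and CHS2, chalcone synthase, 27.7 and 65.9. CHS1 (24.5 and 45.7) and the regulator MYB12 (5.90 and 11.3) differed by less than 2-fold. In the wound and jasmonate list 3 of 9 loci were higher and 1 lower (median −0.39, percentile 11.2), and it gained a call as lower at a filter of 5 FPKM (−0.92, percentile 2.27) and without loci that join several genes (−0.65, percentile 1.52). LOXF, a lipoxygenase gene, read 45.3 and 5.37 FPKM, PI1, a proteinase inhibitor, 18.9 and 48.1, and PPO, polyphenol oxidase, 0.587 and 5.54. CATHDINH was listed at 0 in wild type and at 2.89 in the overexpressor.

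Heat shock and chaperone genes were higher at 7 of 19 loci and lower at 1, with a median of 0.50 at percentile 99.6 (93.6 at equal sums, which ended its call). LEMTSHP, a mitochondrial small heat shock protein gene, read 3.60 FPKM in wild type and 107 in the overexpressor, 23.4-fold higher. HSC70.3 read 1.52 and 17.1 and HSP17.4 read 8.95 and 48.1, whereas SL20.1SHSP was listed at 0 in wild type and at 7.51 in the overexpressor. Ethylene genes were higher at 7 of 19 loci and lower at 3 (median 0.52, percentile 98.3). ACO4 and ACO1, ACC oxidase genes whose enzymes make ethylene, read 3.54 and 40.1 FPKM and 10.9 and 55.2 FPKM. A response factor gene, ERF1 on chromosome 6, read 0.742 and 5.64. The list percentile was 97.2 at a pseudocount of 0.1 and 93.7 at equal sums, which ended its call.

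Growth-related genes were not lower as groups. In cell expansion and wall loosening, 6 of 25 loci were higher and 2 lower, with a median of 0.42 at percentile 99.8. EXLA1, an expansin-like gene, read 17.1 FPKM in wild type and 150.0 in the overexpressor, 8.35-fold higher. The xyloglucan-modifying enzyme genes TXET-B1 (0.611 and 15.4), TXET-B2 (0.691 and 18.0) and XTH16 (51.2 and 224) were higher too. Without loci that join several genes the median was 0.07 at percentile 90.5, so this call was lost. Among 18 cell division loci 3 were higher and none lower, with a median of 0.43 at percentile 99.9. These were the mitotic cyclins CYCB1.1 (3.38 and 15.3) and CYCB1 (17.3 and 41.5) and a CYCD3 locus on chromosome 1 (9.26 and 38.9). CYCA1 read 7.76 and 16.1, just under the limit. Auxin response genes were higher at 4 of 23 loci and lower at none (median 0.18, percentile 90.8). The list gained a call as higher at a filter of 5 FPKM (0.28, percentile 98.7) and at equal sums (1.37, percentile 98.1). ARF5 (1.71 and 11.3) and IAA11 (3.87 and 13.4) differed most, followed by IAA10 (11.4 and 26.4) and ARF13-1 (6.79 and 15.8).

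Markers of other cell types gave no single direction. Of 13 epidermis and trichome loci, 3 were higher and 3 lower (median 0.20, percentile 87.5). The lipid transfer protein genes LTPG2 (105 and 651 FPKM) and TSW12 (156 and 547) were higher, and the terpene synthase genes TPS41 (60.5 and 25.5) and TPS7 (11.8 and 5.10) were lower. In the meristem list TKN2 (6.61 and 3.47) and LET12 (198 and 121), and in the xylem list XSP10 (6.32 and 9.56), differed by less than 2-fold. Reference genes stayed within 2-fold at all 10 loci on the deposited scale (median −0.30, percentile 65.9), although their median was 2.19 at equal sums. The actin loci ACT read 384 and 270 FPKM on chromosome 3 and 252 and 251 on chromosome 11, both GAPDH loci 173 and 130 and 758 and 588, and UBI3 1153 and 984.

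Across all loci of 1 gene with a symbol (identifier-only loci such as Solyc12g013710.1 left aside), the largest differences without a value of 0 were those of LEODD (chromosome 12, 888698 to 891079), at 2.45 FPKM in wild type and 590 in the overexpressor, and of SODB, the iron superoxide dismutase gene (chromosome 6, 27497624 to 27500186), at 5745 and 286. ER24 (2.75 and 192), LE25, a late embryogenesis abundant protein gene (1.31 and 88.6), LEMTSHP, CTU1 (4.22 and 104), KRP2, a cyclin-dependent kinase inhibitor gene (1.504 and 43.3), SAP11 (4.06 and 86.6) and CHI3 followed LEODD. On the lower side, INPS (4137 and 246) and CA2 (6334 and 476) stood beside the CAB genes and PSBQ. The values of CTU1, KRP2 and SAP11 enter only because genes at 0 were set aside, which was decided after the values were seen. Of the genes at 0, LECNX61.0 was listed at 0 in wild type and at 116222 FPKM in the overexpressor, TMC at 0 and 63.6, HCR2-0B at 0 and 55.5, RNALE at 0 and 37.2, and LYSRS at 0 and 32.6. SP5G, a relative of the florigen gene, was listed at 1937 FPKM in wild type and at 0 in the overexpressor. LYSRS encodes lysyl-tRNA synthetase, which every cell uses, so a 0 is given only as listed. Of the 2043 higher loci 251 were listed at 0 in wild type, and of the 2647 lower loci 15 were listed at 0 in the overexpressor.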

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

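The tests on fragment length given here were chosen only after their result had been seen. Loci without a gene were outside the comparison of genes. Of 4382 with a mean of at least 1 FPKM, 1137 were at least 2-fold higher in the overexpressor and 698 were lower. Their median difference was 0.20. Their median span was 415 bp, and 1376 spanned less than 300 bp. No control library bears on this excess of higher loci, which was set against a level of 0. How the loci without a gene were delimited is not given in the sources used here. If reads of these 2 libraries delimited them, the deeper overexpressor (depth ratio 1.91) could favour loci higher in it. The level of 0 therefore cannot decide whether the excess means anything.

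Within these loci the short ones stood apart: over 388 loci of 120 to 190 bp the median log2 ratio was −0.04, against 0.24 over 2206 loci of 300 bp or more, a difference of −0.28 (95% bootstrap interval −0.47 to −0.15, 2000 resamples). An unequal length correction between the libraries would make the steps of 1 fragment diverge at short loci, and they did, with a ratio of 2.52 between libraries at short loci and 1.91 at long ones; the predicted shift of −0.40 lay inside the interval, so it is a candidate explanation for the short loci. Different mean fragment lengths are argued against as what made it unequal, since the fitted length offsets differed by 0.245 bp (0.235 to 0.255), while the step ratios would need 7.52 bp (median) and at least 0.38 bp. What else made it unequal, such as another spread of lengths, was not tested. The excess of higher loci at 300 bp and more stays open, and the genotype was not tested for it.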

How the results depend on the processing

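The settings without loci at 0, without loci joining several genes, with named members only and with random lists from the 50 loci nearest in mean expression were chosen after seeing the data. No paired analysis was possible because each genotype had 1 library. Scaling to equal medians, to equal upper quartiles or by a trimmed mean of log ratios, unmatched random lists, and leaving out loci at 0 kept the call of every list and both counts within 1.5 times. Gibberellin perception, at −0.01 with no call, became 0.0082 at equal medians, 0.047 with the trimmed mean and 0.23 at equal upper quartiles. Depth limits low genes most, since 1 FPKM over 1 kb rests on 7.47 fragments in wild type. The 4-fold limit left 606 higher and 626 lower loci. A filter at 5 FPKM left 1249 higher and 2458 lower loci, so that higher loci were 33.7% of calls, against 43.6%. The loci it removed thus held more higher than lower calls, for a reason that was not tested. The same filter brought the wound and jasmonate list to −0.92 (percentile 2.27) and the auxin list to 0.28 (98.7). Without the 100 most abundant genes 4776 loci were higher and 1133 lower, and 17 of 107 named loci came under 2-fold, against 7 at equal upper quartiles.

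For other settings that changed a call the cause was not tested. The ethylene list had a median of 0.53 at both smaller pseudocounts (percentiles 97.2 and 97.1), and gibberellin synthesis one of −0.68 without a filter. With fixed identifiers only, which kept just loci shown without a symbol, the isoprenoid list was at −1.27 (6 loci) and the carotenoid list at −0.95 (4 loci). With named members only the cleavage list was at −0.56. Without loci joining several genes, cell expansion was at 0.066 and wound and jasmonate at −0.65 (percentile 1.52). With the 50 nearest loci the photosystem list (median −2.35, unchanged) was at percentile 8.60 and the Rubisco list (−2.41, unchanged) at 3.33, both without a call. These draws did not leave out the lists' own loci. Other medians moved over 1.5 times with a call kept. Without the 100 most abundant genes these were chlorophyll synthesis (−1.67 to −1.01), the isoprenoid list (−1.36 to −0.71), carotenoids (−1.49 to −0.84), cleavage (−0.92 to −0.27), cell division (0.43 to 1.08), cell expansion (0.42 to 0.91), heat shock (0.50 to 1.11), ethylene (0.52 to 1.17) and flavonoid genes (1.05 to 1.69). At equal upper quartiles cell division was at 0.67 and cell expansion at 0.65, and at equal sums they were at 2.01 and 1.70 and flavonoid genes at 2.31. Pathogenesis-related genes were at 1.33 with named members only. With fixed identifiers only flavonoid genes were at 2.25 (5 loci) and the cleavage list at −2.04 (3 loci).

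Equal sums reversed most lower results by construction: a 34 bp locus without a gene (chromosome 2, 39580471 to 39580504) held 89.8% of the wild-type sum and 43.2% of the overexpressor sum, which gave a log2 scaling factor of 2.92 before 1 is added, so that low loci moved less (the median of all loci went from −0.05 to 1.08). It gave 9541 higher and 24 lower loci. List medians became 1.07 for chlorophyll synthesis, 1.24 for the isoprenoid list, 1.099 for carotenoids, 0.70 for cleavage, 0.54 for gibberellin synthesis, 0.23 for light-harvesting, 0.57 for photosystem and 0.51 for Rubisco genes. Gibberellin perception reached 1.80 (percentile 99.0) and auxin response 1.37 (98.1), while heat shock at 1.27 and ethylene at 1.07 lost their place. Of 107 named loci 45 changed sign, 33 of them at least 2-fold lower on the deposited scale, which follow. Carotenoid genes became CYP97C11 1.49, PSY1 1.28, ZDS 1.26, LCY1 1.18, PSY2 1.15, CYP97A29 1.11, CRTR-B1 1.09, CRTISO 1.05, PDS 0.93, LCY-E 0.90 and ZE 0.051. Other pigment and hormone genes became GGR 0.89, DXS 0.73, CYP707A1 0.70, GGPS2 0.35, GA2OX2 0.14, NCED1 0.14 and GA20OX1 0.12. Photosynthesis genes became SBPASE 0.66, PSBP 0.54, PSBS 0.44, PSBO 0.32, RBCS-1 0.32, RBCS-2A 0.30, RBCS-3B 0.17, CAB1B 0.025 and PSBQ 0.022. The rest were COP1 1.41, TPS41 1.05, PHYB2 0.95, PHYE 0.76, PR-5 0.71 and TPS7 0.43.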

Other observations

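Of the tests given here, all on the pigment genes and on the loci at 0 were chosen only after the result had been seen, and the superoxide dismutase test was written before SODCC.5 and CCS had been looked up. Superoxide dismutase genes differed in opposite directions. SODB, the iron enzyme, was 20.04-fold lower in the overexpressor (5745 FPKM in wild type, 286 in the overexpressor), while the copper/zinc enzyme gene SODCP.2 (chromosome 11, 49246051 to 49251754) was 6.80-fold higher at 54.2 and 374, and SODCC.5 (chromosome 1, 69074003 to 69078931) 3.69-fold higher at 73.6 and 274. The genes SODCP.2, SODCC.5 and CCS were chosen outside the rule for named genes, SODCP.2 after its values had been seen. As a hypothesis, a copper-dependent switch between these enzymes may be at work, which would raise SODCC.5 and the copper chaperone CCS alike. CCS differed by 0.10 on the log2 scale (63.2 and 67.9 FPKM), short of the 2-fold rise required and not below 0, and PETE, plastocyanin and itself a copper protein, was lower at 5203 and 1299 FPKM, as the photosystem list was, which goes the other way; the question stays open.

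Gene names of the plastid genome stood at 14 loci with nuclear positions, 12 of them between 1844954 and 1894905 on chromosome 1. They were chosen after their names were seen. Of the 14, 4 were at least 2-fold lower, 1 was higher and listed at 0 in wild type, and the median was 0.10, beside −2.35 for the photosystem list. ATPB, named for a subunit of the plastid ATP synthase, read 35.6 FPKM in wild type and 6.82 in the overexpressor there, and RPS18 read 254 and 271. Reads of the plastid genome itself were not analysed here.

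The lower level of pigment and photosystem genes was weighed over 73 loci of the chlorophyll, carotenoid, light-harvesting and photosystem lists, with a median of −1.93 and an upper quartile of −1.37. A scale set by a few abundant transcripts would move every gene by the same factor, but all other gene loci had a median of −0.046 (quartiles −0.59 and 0.47). This concerns only the gap between the 73 loci and the others, which the low percentiles of these lists had already shown. It cannot tell whether the 73 loci are lower in level, which depends on the scaling. The chlorophyll, carotenoid, light-harvesting and photosystem medians stayed below 0 in every scaling used except equal sums. There they became 1.07, 1.099, 0.23 and 0.57, with a single locus without a gene holding 89.8% of the wild-type sum. The median of all gene loci was 0.56 when scaled without the 100 most abundant genes and 1.08 at equal sums. A general lower level of abundant genes has values on its side, since of 249 other loci with a mean of at least 1000 FPKM 134 were lower and 13 higher (median −1.11), but as the whole cause it is argued against, since 10000 random lists from the 50 nearest loci outside the 73 reached −1.43 at the lowest (the bound was first the upper quartile of the 73 loci, which left the question open, and was changed to their median after the values were seen). For the photosystem list alone a general lower level of abundant genes stays a candidate explanation, as the list median lay at percentile 3.54 of such lists. The draw cannot decide it, since photosynthesis loci outside the 73, such as SBPASE and the RBCS genes, stayed among the loci drawn from. They also count among the 249 loci. Harvest at another time of day may contribute: 4 of 7 clock loci differed at least 2-fold, and 11.2% of random lists held as many, which decides nothing; with 1 library each, the genotype remains an untested explanation.

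More loci stood at 0 in wild type than in the overexpressor, 305 against 15 among gene loci, and 82 of the 305 read 10 FPKM or more in the overexpressor. Lower depth in wild type was weighed on 2396 gene-free loci of 300 bp or more, where counting alone predicted 28.1 zeros and 164 were seen. For the overexpressor the same prediction was 31.4 zeros and 12 were seen, so it missed there in the other direction. Lower depth would leave no zeros at loci with 20 or more fragments in the overexpressor. Yet 46 of 1138 such loci were at 0, which argues against depth as the whole cause. Estimates that failed and were written as 0 would heap up at 0 alone, but 31, 26 and 27 loci stood at 1, 2 and 3 fragments beside the 46. The excess over the 31 is small; a requirement that it exceed its spread was added after both counts were seen and turned the reading from against to open.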
